A study of Mus musculus with 6 samples.

How the data were processed

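Primary hepatocytes of male wildtype mice on a C57Bl6/J background, 10 weeks old per the labels, had been treated with the vehicle DMSO or with 1 of 2 agonists of the nuclear receptor PPAR-delta, KD3010 or GW1516. Each of the 3 groups held 2 arrays, which the labels call technical replicates. Doses and treatment times were not given in the sources used here. RNA had been extracted with Trizol, cleaned on columns with DNase digestion and converted to biotin-labelled cRNA, per the labels' protocols, and hybridised to Illumina mouse bead arrays with 25697 probes.

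The deposited table of unnormalized values holds a mean bead intensity per probe on a linear scale, per the file headers, and GenomeStudio is named in the submitters' processing notes, with no version given. The deposited detection p-value beside each intensity, per the file headers, gives the chance that a probe is no brighter than the negative controls. A second deposited table holds intensities that the authors had normalized between arrays by a method not given in the sources used here. Its 6 named columns equalled the series matrix values (largest difference 0), so both give the same results below. The medians of the 6 series matrix columns lay between 257.8 and 257.9, on a linear scale without centring. A further 1 column of that table has no name and was not used. The columns of the unnormalized table name the group and a letter. Their bead counts per probe equalled those of the same group and letter in the normalized table for 100% of probes, and at most 4.54% with any other array. The equal values then tie array A of each group to replicate 1 of the labels and array B to replicate 2.

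Intensities were background-corrected with the normexp model, fitted on the detection p-values, with an offset of 16, then quantile-normalized and taken to log2 in limma 3.58.1 (R 4.3.3). Probes detected at p below 0.05 on both arrays of at least 1 group were kept, which left 10530 probes. Gene symbols came from the platform annotation and were updated through Entrez identifiers or accessions. Of the 25697 probes, 23978 had 1 symbol, 0 had several and 1719 are unnamed here. A total of 23962 probes were named through the Entrez identifier, 9 through the accession and 7 kept the array's symbol. Each gene was represented by its brightest kept probe, which gave 8058 tested features, 7457 named genes and 601 unnamed probes. Of the tested genes named by the rule below, Acadl and Hilpda had a further detected probe, and it had the same direction against DMSO in both genes.

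A linear model over all 6 arrays was fitted with lmFit and eBayes, with 3 residual and 6.54 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 8058 features of a comparison, and a gene was called at an adjusted p below 0.05 with a change of at least 1.5-fold. Errors of log2 changes are standard errors and intervals are 95% confidence intervals. A probe not detected on either array of a group has only a bound there, on the background-corrected scale. Its fold is given as at least N-fold, from the brighter group's mean against the higher of the lowest detected signal and the probe's own signal on each array of the dimmer group. The 2 arrays per group limit the precision. Since the labels call them technical, the p-values of single genes measure the spread between arrays and not between cultures or animals.

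Before the data were examined, 32 lists of pathway genes and cell type markers were fixed, and 600 of their 674 entries had a named probe. The 26 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with fry and an estimated correlation beside it. At the preset correlation camera compares the genes of a list with all other genes, so genes and not arrays act as its replicates. With an estimated correlation camera uses the 3 residual degrees of freedom of the fit. The median of a list was also placed among 10000 random lists matched on mean expression. The genes named were fixed by a rule: the 8 largest rises and the 8 largest falls called in a comparison with the arrays of both groups apart, up to 3 called genes of each list (6 in the lists of PPAR targets, fatty acid oxidation and fibrogenesis), and in every case Angptl4, Pdk4, Plin2, Cpt1a, Acadl, Fgf21, Cyp4a10, Cyp4a14, Ppard, Ppara, Pparg and Ctgf, which now has the symbol Ccn2. Some genes of that last group are not reported here. Other genes named were chosen after their values were seen, among them all list members given with a p adjusted over the list alone. The adjustment over the 8 tested genes of the last group was computed after the results over all genes were seen, as were the tests of lists without the members shared with the PPAR target list.

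The fit was tested on simulated data for the comparison of KD3010 with DMSO, with 200 of 8058 genes changed in each of 20 simulations. With gene variances drawn from the fitted prior, 99.1% of 4-fold, 65.2% of 2-fold and 7.14% of 1.5-fold changes were called, and 5.48% of the calls were false. With each gene's moderated variance taken as its true one, 100% of 4-fold, 91.7% of 2-fold and 26% of 1.5-fold changes were called, and 7.20% of the calls were false, above the nominal share. In each case camera's unadjusted p was below 0.05 for 20 of 20 lists of 20 genes shifted by 0.5 on the log2 scale. It was below 0.05 for 1 of 20 unshifted lists. The genes were simulated as independent, so this does not test camera on correlated genes.

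Alternatives covered the background correction, the normalization, the filter on dim probes, the handling of several probes per gene, the variance model, the arrays in the fit, the threshold, the set test, and leaving out each array. They were not all distinct. The authors' table and the series matrix hold the same values, and dropping the fold minimum or raising it to 2-fold changed no call. Counts of alternatives below include these. The replicate number was fitted as a block on the main values, and also on the series matrix values, a pairing of choices that was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.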

Results

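Genome-wide expression was measured on 6 bead arrays of primary mouse hepatocytes, 2 each after treatment with the vehicle DMSO, with KD3010 or with GW1516, both agonists of PPAR-delta, a nuclear receptor that regulates fatty acid use. The labels call the 2 arrays of a group technical replicates. Between 10239 and 10805 of the 25697 probes were detected per array, at mean signals between 953.2 and 1157 and a mean background between 227.1 and 240.5. Arrays of one group correlated at 0.991 for DMSO, 0.990 for KD3010 and 0.989 for GW1516 across the 8058 tested features. Array B of GW1516 lay slightly closer to array A of DMSO (0.9895) than to array A of its own group (0.9893). Hepatocyte markers were at a median log2 level of 12.95, with 14 of 18 detected on all 6 arrays. Of 14 Kupffer cell markers and 12 lymphocyte markers, 0 were detected on all 6 arrays, against 10 of 15 sinusoidal endothelial markers and 3 of 14 stellate cell markers.

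The first comparison asked how KD3010 changed hepatocyte expression. Plin2, which coats lipid droplets, rose 4.18-fold, from a log2 signal of 10.55 ± 0.31 to 12.62 ± 0.57 (SD, n = 2 arrays each). Creb3l3, a liver transcription factor of fasting lipid metabolism, rose 4.14-fold, from 8.93 ± 0.13 to 10.98 ± 0.03. Pdk4, a kinase that restrains pyruvate oxidation, rose 3.80-fold, and Hilpda, a lipid droplet protein, rose 3.11-fold.

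In limma's test 10 of 8058 features were called between KD3010 and DMSO, 8 higher and 2 lower, and 983 had an unadjusted p below 0.05, where 403 would be reached by chance. The log2 change was 2.06 ± 0.26 (SE) for Plin2 (adjusted p = 0.0209), 2.05 ± 0.17 for Creb3l3 (adjusted p = 0.00427), 1.93 ± 0.21 for Pdk4 and 1.64 ± 0.18 for Hilpda (adjusted p = 0.0112 for both). Rad54b, a DNA recombination factor, rose 3.05-fold (adjusted p = 0.0328) and Nceh1, a cholesterol ester hydrolase, 2.17-fold (adjusted p = 0.0424). Ifnk, a type I interferon, rose 2.52-fold and Ivl, a protein of the epidermal cornified envelope that was not detected on the DMSO arrays, at least 2.17-fold after background correction (adjusted p = 0.0148 for both). Neither was called without background correction, where Ifnk was 1.40-fold (adjusted p = 0.0717) and Ivl 1.38-fold higher (adjusted p = 0.0902), or with the authors' normalized values, where Ifnk was 1.44-fold (adjusted p = 0.0405, below the fold minimum) and Ivl 1.42-fold higher (adjusted p = 0.0572). Rad54b stayed called without background correction, at 2.03-fold. The hormone precursor gene Guca2a was 2.74-fold lower (adjusted p = 0.0148), and Scnn1a, a subunit of the epithelial sodium channel, was 2.22-fold lower (adjusted p = 0.0322) and 1.69-fold lower without background correction. In each of these genes both KD3010 arrays lay beyond both DMSO arrays.

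Of the other genes fixed beforehand, Acadl differed from DMSO by 0.67 ± 0.17 on the log2 scale (adjusted p = 0.218) and by 1.18 ± 0.18 on a further, dimmer probe (adjusted p = 0.0581 over all detected probes), Angptl4 by 0.42 ± 0.17 (adjusted p = 0.383), Fgf21 by 0.27 ± 0.16, Ccn2 by 0.08 ± 0.16, Cyp4a14 by 0.06 ± 0.20 and Pparg by 0.02 ± 0.21, and none of them was called. Under median scaling, which moved the median of all genes by -0.12, the values of Cyp4a14 and Pparg turned negative. Cpt1a, Ppard and Ppara were not detected on both arrays of any group. Cyp4a10 was not analysed here.

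As a group, PPAR target genes rose under KD3010, with a median log2 change of 0.29 over 21 tested members (limma's camera, adjusted p = 2.4e-09, percentile 100 among random lists; adjusted p = 0.149 with an estimated correlation). Adjusted over the list alone, 7 members rose and 0 fell, against 4 called over all genes, and besides the called genes these were Acot1 (2.52-fold), Plin5 (2.00-fold) and the carnitine transporter gene Slc22a5 (1.78-fold). Mitochondrial fatty acid oxidation genes rose by a median of 0.31 over 19 members (adjusted p = 4.3e-05, and adjusted p = 0.194 with an estimated correlation), and by 0.20 without KD3010 array B. Adjusted over the list alone, 3 of them rose: Slc22a5, Cpt2 (1.76-fold), an enzyme that releases fatty acids from carnitine in mitochondria, and Acadl (1.60-fold). Over all genes, Cpt2 was called in 7 of 21 alternatives, the authors' normalized values among them, and Slc22a5 in 3. Acot1, Plin5 and Acadl were called in 0, as were Lipe and Acot4, which are named below. The 15 members that are not in the PPAR target list also rose as a group (median 0.31, 14 of 15 positive, limma's camera adjusted p = 0.000168 over 9 such tests). These 9 tests used the preset correlation and were not run with an estimated one. The list of lipid droplet and triglyceride storage genes rose by a median of 0.20 over 15 members (adjusted p = 0.000431, and adjusted p = 0.196 with an estimated correlation), of which Plin2, Plin5, Hilpda and Lipe rose when adjusted over the list alone. The median of the 15 was 0.12 without KD3010 array A, 0.13 without background correction and 0.074 with median scaling, which also lowered the median to 0.19 for PPAR target genes and 0.20 for mitochondrial genes, and the lists still passed there. The 10 lipid droplet genes outside the PPAR target list had a median of 0.12 and did not pass (limma's camera adjusted p = 0.311). Peroxisomal fatty acid oxidation genes had a median of 0.07 over 21 members (adjusted p = 0.346), and Acot4 (1.64-fold) alone rose when adjusted over the list alone. Fibrogenesis and matrix genes had a median of -0.11 over 16 members (adjusted p = 0.653), and 0 passed when adjusted over the list alone. With an estimated correlation 0 of the 26 lists passed. The estimates were -0.038 for PPAR target, -0.039 for mitochondrial and -0.029 for lipid droplet genes, below the preset 0.01. These lost calls therefore do not show a correlation among the genes above the preset. They came with the 3 residual degrees of freedom that this version of camera uses, so the few arrays limited it.

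Among stellate cell markers Vim was 1.74-fold higher with KD3010 (limma adjusted p = 0.0271, adjusted over the list alone of 4 tested markers, and adjusted p = 0.251 over all genes, where 1 of 21 alternatives called it), while Acta2 differed from DMSO by -0.27 ± 0.27, Dcn by -0.02 ± 0.18 and Reln by 0.22 ± 0.17 on the log2 scale. The only tested Kupffer cell marker, Ctss, differed by 0.60 ± 0.29. Sinusoidal endothelial markers had a median of -0.05 over 11 tested genes with KD3010 (adjusted p = 0.882) and 0.13 with GW1516 (adjusted p = 0.679). The count of called genes ranged from 0 to 49 across the alternatives, and leaving out an array gave 1 without DMSO array A (Pdk4), 0 without DMSO array B, 2 without KD3010 array A (Creb3l3 and Plin2), 2 without KD3010 array B (Creb3l3 and Ddx5), 1 without GW1516 array A (Creb3l3) and 6 without GW1516 array B (Creb3l3, Guca2a, Hilpda, Ivl, Pdk4 and Rad54b). Creb3l3 kept its call in 19 of 21 alternatives and lost it without either DMSO array (adjusted p up to 0.0842), while the call was lost in 8 of 21 for Plin2, 6 for Pdk4, 7 for Hilpda and for Guca2a, 10 for Rad54b and for Scnn1a, 11 for Nceh1, and in 11 of 20 for Ivl and 12 of 20 for Ifnk.

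**Figure D1:**
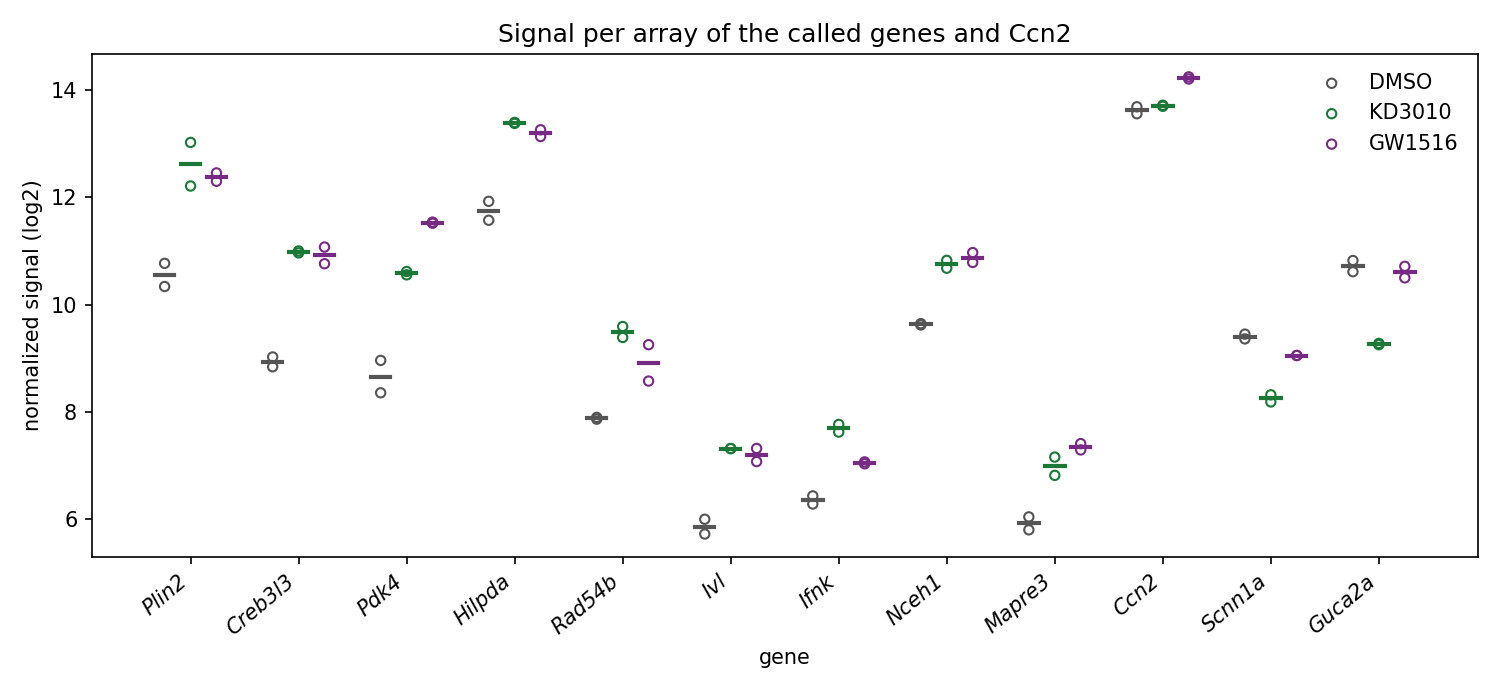
Normalized log2 signal (vertical axis) of 12 genes (horizontal axis) on each array, where circles are the 2 arrays of a group and bars their means, with DMSO in grey, KD3010 in green and GW1516 in purple. Pdk4 lies at 8.66 with DMSO, 10.59 with KD3010 and 11.53 with GW1516, and Guca2a at 10.72, 9.27 and 10.61.

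The second comparison asked the same of GW1516. Pdk4 had the largest called change, 7.29-fold, from a log2 signal of 8.66 ± 0.43 to 11.53 ± 0.01 (SD, n = 2 arrays each). Creb3l3 rose 3.95-fold, Hilpda 2.72-fold and Nceh1 2.37-fold. Plin2 was 3.54-fold higher and just missed the threshold (adjusted p = 0.0507).

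In limma's test 7 of 8058 features were called between GW1516 and DMSO, 7 higher and 0 lower, and 767 had an unadjusted p below 0.05, where 403 would be reached by chance. The log2 change was 2.87 ± 0.21 (SE) for Pdk4 (adjusted p = 0.000964), 1.98 ± 0.17 for Creb3l3 (adjusted p = 0.00285), and 1.45 ± 0.18 for Hilpda and 1.24 ± 0.16 for Nceh1 (adjusted p = 0.0261 for both). Mapre3, which binds growing microtubule ends, and Ivl were not detected on the DMSO arrays and rose at least 2.22-fold and at least 1.99-fold after background correction (adjusted p = 0.0261 for both). Neither was called without background correction, where Mapre3 was 1.38-fold (adjusted p = 0.125) and Ivl 1.34-fold higher (adjusted p = 0.176), or with the authors' normalized values, where they were 1.41-fold (adjusted p = 0.0977) and 1.37-fold higher (adjusted p = 0.129). The remaining called feature is an unnamed probe that rose 2.28-fold. Both GW1516 arrays lay above both DMSO arrays in each named gene.

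Of the other genes fixed beforehand, Acadl differed from DMSO by 0.98 ± 0.17 (adjusted p = 0.162), Ccn2, the profibrotic connective tissue growth factor gene, by 0.60 ± 0.16 (adjusted p = 0.337), Angptl4 by 0.46 ± 0.17 (adjusted p = 0.458), Fgf21 by 0.43 ± 0.16 (adjusted p = 0.456), Cyp4a14 by 0.30 ± 0.20 and Pparg by -0.01 ± 0.21 on the log2 scale. The dimmer probe of Acadl differed by 1.42 ± 0.18 (limma adjusted p = 0.0327 over 10530 probes), and with the mean of a gene's probes Acadl was called at 1.20 (adjusted p = 0.0371). Adjusted over the list alone of the 8 tested genes fixed beforehand, Pdk4 and Plin2 included, 6 passed with GW1516, namely Pdk4, Plin2, Acadl, Ccn2 (limma adjusted p = 0.00686), Angptl4 and Fgf21 (adjusted p = 0.0337 for both), and 3 passed with KD3010, namely Pdk4, Plin2 and Acadl (adjusted p = 0.00923). This adjustment was computed after the results over all genes were seen.

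PPAR target genes rose under GW1516 by a median log2 change of 0.59 over 21 members (limma's camera, adjusted p = 4.7e-14, and adjusted p = 0.0823 with an estimated correlation). The median was 0.36 without background correction or with the authors' values and 0.31 with no filter on dim probes, and the list still passed. Adjusted over the list alone, 10 members rose and 0 fell, against 3 called over all genes, among them the peroxisomal enzyme gene Ehhadh (2.53-fold) and the acyl-CoA thioesterase gene Acot2 (2.17-fold). Mitochondrial fatty acid oxidation genes rose by a median of 0.38 over 19 members (adjusted p = 7.6e-09, and adjusted p = 0.0869 with an estimated correlation; 0.25 with median scaling, adjusted p = 1.1e-08), with Acot2, Acadl (1.98-fold), Cpt2 (1.77-fold), Slc22a5 (1.70-fold), Eci2 (1.65-fold) and Etfdh (1.63-fold) passing when adjusted over the list alone. The 15 members outside the PPAR target list also rose as a group (median 0.28, 15 of 15 positive, limma's camera adjusted p = 7.7e-07, at the preset correlation alone). The lipid droplet list rose by a median of 0.42 over 15 members (adjusted p = 0.00164, and adjusted p = 0.245 with an estimated correlation), with Plin2, Hilpda, Cidec and Mgll higher and Cideb, another lipid droplet protein gene, lower (log2 change -0.74 ± 0.28) when adjusted over the list alone. The median of the 15 was 0.23 without GW1516 array A, 0.24 without DMSO array B, 0.17 without background correction and 0.19 with the authors' values or with no filter on dim probes, and the list still passed there, while without GW1516 array B it did not pass (median 0.38, adjusted p = 0.0612). The 10 members outside the PPAR target list had a median of 0.10 and did not pass (limma's camera adjusted p = 0.589). Peroxisomal fatty acid oxidation genes passed with a median of 0.07 and a mean of 0.20 over 21 members (limma's camera, adjusted p = 0.0326, and adjusted p = 0.354 with an estimated correlation). That median lay at percentile 82.9 among random lists. It was 0.12 with either other filter on dim probes and 0.17 with the mean of a gene's probes. With median scaling, which moved the median of all genes by -0.09, it was -0.04 and the list still passed (limma's camera, adjusted p = 0.0133). This list did not pass without DMSO array A (adjusted p = 0.123), DMSO array B (0.0597), GW1516 array A (0.0839) or GW1516 array B (0.0612), although the median was higher in those fits, at 0.12, 0.20, 0.081 and 0.17. Its 19 members outside the PPAR target list had a median of 0.05 and did not pass (limma's camera adjusted p = 0.220). Ehhadh, Acot4 and Acaa1b rose when adjusted over the list alone. Fibrogenesis and matrix genes had a median of 0.01 over 16 members (adjusted p = 0.991). With an estimated correlation 0 of the 26 lists passed. The estimates were again below the preset 0.01, at -0.038 for PPAR target, -0.039 for mitochondrial, -0.037 for peroxisomal and -0.029 for lipid droplet genes. The 3 residual degrees of freedom limited this version of camera here too.

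The count of called genes ranged from 0 to 20 across the alternatives, and leaving out an array gave 1 without either DMSO array (Pdk4), 8 without KD3010 array A, 5 without KD3010 array B, 0 without GW1516 array A and 2 without GW1516 array B (Creb3l3 and Pdk4). Pdk4 kept its call in 20 of 21 alternatives and lost it without GW1516 array A (adjusted p = 0.0732), and with the authors' normalized values Plin2, Acadl, Ccn2, Ehhadh and Cpt2 were also called. Plin2 was called in 10 of 21 alternatives, Acadl in 7, Ehhadh and Cpt2 in 6 and Ccn2 in 4. For Ccn2 these were the authors' table, the equal series matrix values with and without the replicate block, and the trended robust variance. Of the other list members named above, Acaa1b was called in 1. Acot2, Slc22a5, Eci2, Etfdh, Cidec, Mgll, Cideb and Acot4 were called in 0. The call was lost in 3 of 21 for Creb3l3, 7 for Hilpda and 10 for Nceh1, and in 12 of 20 for Mapre3 and 14 of 20 for Ivl.

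**Figure D2:**
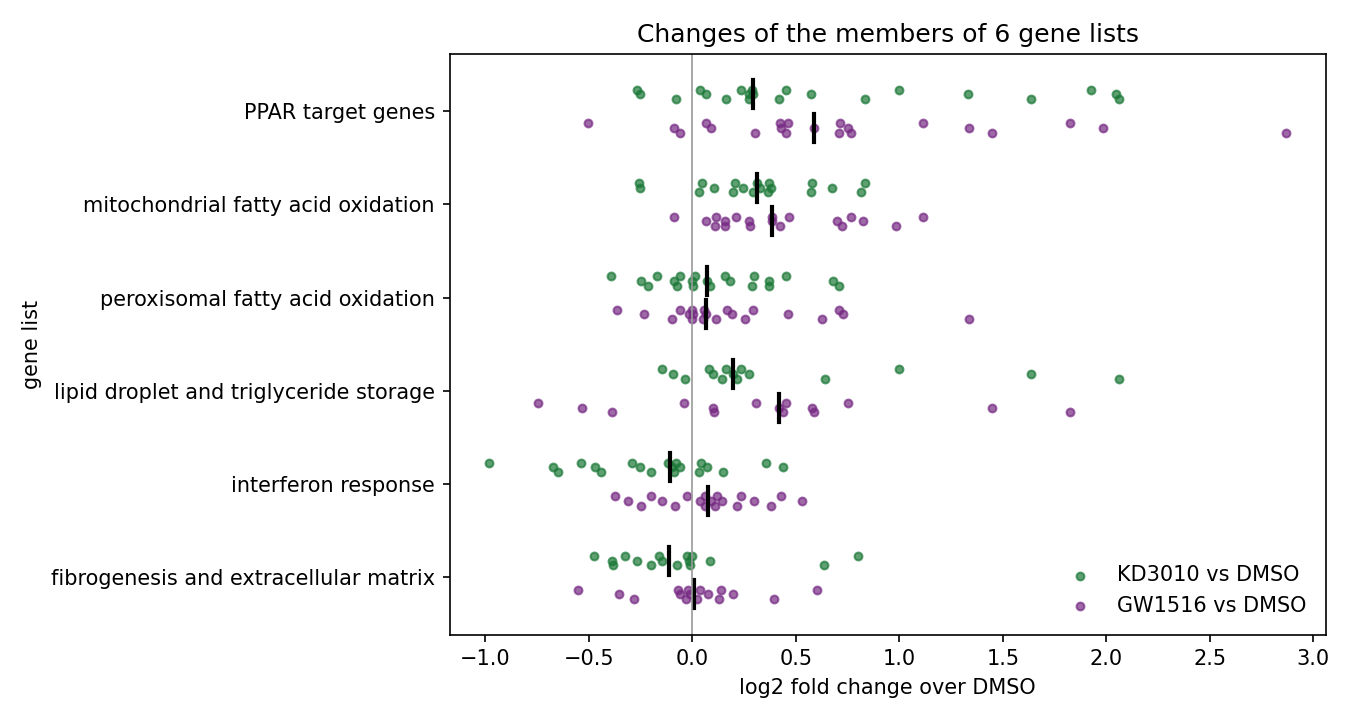
Log2 fold change over DMSO (horizontal axis) of each tested member of 6 gene lists (vertical axis), where each dot is a gene, black bars are list medians, green is KD3010 and purple is GW1516. The PPAR target genes have medians of 0.29 and 0.59 and the interferon response genes medians of -0.11 and 0.08.

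The third comparison set the agonists against each other. Doses and times of both were not given in the sources used here, so whether they matched is not known. Pdk4 was 1.92-fold lower with KD3010 than with GW1516, a log2 difference of -0.94 (95% interval -1.40 to -0.48), and Ccn2 was 1.43-fold lower, -0.52 (-0.87 to -0.17). Guca2a was 2.53-fold lower with KD3010. Over all genes 0 differences passed in limma's test at the settings used.

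In limma's test 0 of 8058 features were called between the agonists, the adjusted p = 0.0624 was the smallest, and 1122 features had an unadjusted p below 0.05, where 403 would be reached by chance. For Pdk4 the adjusted p was 0.148 over all genes and 0.00941 adjusted over the list alone of the 8 tested genes fixed beforehand, and 7 of 21 alternatives called it over all genes. For Ccn2 these were 0.227 and 0.0325, and 0 alternatives called it. Among the 16 tested fibrogenesis genes, Vim alone passed when adjusted over the list alone (log2 difference 1.35 ± 0.23, limma adjusted p = 0.00331), and Ccn2 did not (adjusted p = 0.0650). The SD of Vim over the 2 GW1516 arrays was 0.50. Most of the list leaned the other way, with 13 of 16 genes lower with KD3010, but it did not pass (median -0.19, limma's camera adjusted p = 0.457). The log2 difference was 0.06 for Creb3l3 (95% interval -0.32 to 0.45), 0.19 for Hilpda (-0.20 to 0.58), 0.24 for Plin2 (-0.35 to 0.83) and -0.13 for Nceh1 (-0.49 to 0.24). Differences of the size at either end of these intervals are not excluded. For the genes called with KD3010 and not with GW1516, the difference was -1.34 ± 0.17 for Guca2a (adjusted p = 0.0624, called in 7 of 21 alternatives), -0.80 ± 0.16 for Scnn1a (adjusted p = 0.146, called in 3), 0.64 ± 0.16 for Ifnk (adjusted p = 0.165) and 0.58 ± 0.22 for Rad54b (adjusted p = 0.302). Mapre3, called with GW1516, differed by -0.36 ± 0.18 (adjusted p = 0.416).

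Among features chosen after their values were seen, the neuropeptide gene Npy was 2.85-fold higher with KD3010 than with GW1516 (adjusted p = 0.0624), the cornified envelope gene Lce1d 2.37-fold higher and the clock gene Per2 2.20-fold lower (adjusted p = 0.0766 for both). The interferon response list was lower with KD3010 by a median log2 difference of -0.23 over 20 members (limma's camera, adjusted p = 0.0468), the only list of 26 that passed camera, and had an adjusted p = 0.730 with an estimated correlation (0.0080, below the preset 0.01). It did not pass fry (adjusted p = 0.0713), where the list of gluconeogenesis and glycolysis genes alone passed (adjusted p = 0.0241, median difference -0.04). It passed without KD3010 array A (adjusted p = 0.0292) and not without DMSO array A (0.0571), DMSO array B (0.0568), KD3010 array B (0.120), GW1516 array A (0.0806) or GW1516 array B (0.143), with medians between -0.28 and -0.20 in these 6 fits, and the median was -0.15 without background correction and -0.14 with the authors' values. Adjusted over the list alone, Ifit2 (2.00-fold lower), Mx1 (-1.10 ± 0.31) and Gbp3 (-0.63 ± 0.18) were lower. PPAR target genes differed by a median of -0.13 (adjusted p = 0.457), with Pdk4 and Ehhadh (-0.88 ± 0.22) lower when adjusted over the list alone. The count of called genes was 0 without each array in turn and between 27 and 57 in the 7 alternatives that called any, among them 39 with the authors' normalized values and 57 with a trended robust variance. Pdk4, Guca2a, Vim, Lce1d, Per2 and Ifit2 were called in each of those 7, Npy in 6, Gbp3 in 5, and Mx1 and Ehhadh in 0.

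The changes of both agonists against DMSO correlated at r = 0.42 (Spearman's rho 0.38) across 8058 genes, which are not independent replicates. Simulations of 3 unchanged groups, with all 6 arrays redrawn at each gene's moderated spread, gave r = 0.50 (0.478 to 0.527 over 100 simulations). A positive r arises there since both comparisons share the simulated DMSO arrays. The share of genes changed in the same direction was 63.1%, against a simulated 66.7%. Both r and this share thus lay below the simulated values, while the covariance lay above. The covariance was 0.0319 against a simulated 0.0193, a difference of 0.0126. That difference depends on the simulated spread, which need not equal the spread of the real DMSO arrays. Creb3l3, Hilpda, Ivl, Nceh1 and Pdk4 were called higher with both agonists, 5 genes where independent lists would share 0.00695 and where the simulations gave at most 1. No gene was changed in those simulations, so they cannot show the overlap that 2 agonists with calls would have. Leaving out an array gave 1 shared gene without DMSO array A, 0 without DMSO array B, 2 without KD3010 array A, 1 without KD3010 array B, 0 without GW1516 array A and 2 without GW1516 array B.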

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

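The 3 tests of explanations in this part were chosen only after the list result was seen, while the list, its test and the alternative settings were fixed beforehand, except for the replicate block on the series matrix values. The detection of cell type markers had been computed together with that list result. The outcome of the test on immune cell markers could thus be known when it was chosen.

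The interferon response list stood out because the agonists differed in the direct test: its median KD3010 minus GW1516 was -0.23 over 20 genes (camera adjusted p = 0.0468), while the medians against DMSO, -0.11 with KD3010 and 0.08 with GW1516, did not pass (adjusted p = 0.0658 and 0.679). Fewer Kupffer cells, macrophages or lymphocytes with KD3010 are argued against by their markers, of which 1 of 26, Ctss, was detected on both GW1516 arrays, while abundant macrophage genes such as Lyz2, C1qa and C1qb were not, but a lower share of sinusoidal endothelial cells stays open, since 10 of 11 tested markers were lower with KD3010 than with GW1516 (median -0.12, camera adjusted p = 0.457). Array B of KD3010 alone stays open: the list's median over the DMSO mean was 0.0059 on array A and -0.22 on array B, and without array B the difference between the agonists was -0.22 with a 95% bootstrap interval over the genes of -0.36 to -0.016, and the call ended (adjusted p = 0.120). The call also ended without DMSO array A (0.0571), DMSO array B (0.0568), GW1516 array A (0.0806) and GW1516 array B (0.143), though the median stayed between -0.28 and -0.20, and it held without KD3010 array A (0.0292). The choice of normalization stays open too: the median was -0.14 with the authors' values (adjusted p = 0.0277) and -0.22 with median scaling (adjusted p = 0.111), the adjusted p ran from 0.0184 to 0.111 over the alternatives of background correction and normalization and from 0.0174 to 0.730 over all alternatives, the highest with an estimated correlation, and a difference between the agonists in the hepatocytes may remain as an untested biological explanation.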

How the results depend on the processing

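With groups of 2 technical replicates, most calls depended on the arrays and settings used, while the directions of the called genes with a symbol held in the alternatives run for each. The cause of the changes below was not tested except where noted. Signal over background limits dim genes such as Ivl and Mapre3, whose DMSO signals were not detected. Slide as a block was not run, because the files used here give no slides. Leaving out 1 array leaves a group with a lone array, which is then assumed to vary like the other groups.

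Genes called for KD3010, GW1516 and the direct comparison were 10, 7 and 0. They were 29, 8 and 37 without background correction, 48, 15 and 45 with normexp on the signals alone at offset 50, 32, 12 and 39 with the authors' normalized table and equally with the series matrix values, 9, 2 and 0 with median scaling, 6, 2 and 0 with no filter on dim probes (more features tested, 18309), 30, 11 and 27 with detection at 0.01 on all 6 arrays (fewer tested, 6357), 49, 17 and 57 with trend and robust variance, 1, 5 and 0 with only the 4 arrays compared, and 1, 2 and 0 with treat against 1.5-fold. The split for KD3010 was 8 higher and 2 lower, against 17 and 15 with the authors' table, 16 and 13 without background correction, and 6 and 3 with median scaling, and for GW1516 it was 7 and 0, against 11 and 1 with the authors' table. For the direct comparison the authors' table gave 16 higher and 23 lower with KD3010. Leaving out single arrays gave 0 to 6 genes for KD3010, 0 to 8 for GW1516 and 0 for the direct comparison.

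Lists passing numbered 3, 4 and 1. With an estimated correlation in camera they were 0, 0 and 0. The direct count was also 0 with median scaling, with detection at 0.01 on all 6 arrays and with only the 4 arrays compared. Without single arrays they ranged from 3 to 4, from 2 to 4 and from 0 to 1. Genes called with both agonists were 5, and 10 with normexp at offset 50, 8 with the authors' table or the series matrix values, 2 with median scaling, 2 with no filter, 10 with trend and robust variance, 1 with only the 4 arrays compared, 1 with treat, and 0 to 2 without single arrays. The correlation between the agonists' changes ranged from 0.351 to 0.555 without single arrays, where 0.555 and 0.545 came from leaving out DMSO array A or B.

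Median scaling moved the median of all genes by -0.12 for KD3010 and -0.09 for GW1516, and reversed Cyp4a14 (-0.071) and Pparg (-0.12) with KD3010 and Pparg between the agonists (-0.029), all uncalled. Without single arrays, uncalled genes that changed sign ranged from -0.21 to 0.34 for Cyp4a14 and -0.16 to 0.21 for Pparg with KD3010, from -0.23 to 0.21 for Pparg with GW1516, and between the agonists from -0.19 to 0.11 for Angptl4, -0.17 to 0.65 for Plin2, -0.52 to 0.036 for Cyp4a14 and -0.19 to 0.25 for Pparg.

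The replicate block gave 9, 3 and 0 called genes, 3 of them with both agonists, and 3, 4 and 1 lists. On the series matrix values, a pairing of choices added after seeing the data, it gave 38, 20 and 45 called genes, 9 with both agonists, 5 lists for KD3010 and 2 for the direct comparison. Same-numbered arrays deviated together with correlations of -0.014, -0.0087 and 0.018 across 10530 probes, so no pairing by number was seen. Correlations over all probes cannot exclude a pairing that moves few of them.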

Other observations

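The test of an intensity trend and the single genes outside the fixed rule were chosen only after their results were seen, and the epidermal and keratinocyte lists were written after the pattern was noticed but before their values were.

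KD3010 also lowered genes outside lipid metabolism when adjusted over the list alone, though at the settings used not over all genes. Mt2, a metal-binding stress protein, was lower by a log2 change of -1.37 ± 0.21 (adjusted p = 0.0551 over all genes) and with GW1516 by -0.86 ± 0.21. The acute phase gene Cp was lower by -0.89 ± 0.15, the glucose metabolism genes G6pc by -0.62 ± 0.16 and Pfkl by -0.75 ± 0.18, the survival factor Mcl1 by -0.88 ± 0.18 and the deacetylase Sirt1 by -0.90 ± 0.25. Gstm3, a glutathione transferase, was higher by 1.21 ± 0.25 and the coactivator Ppargc1b by 0.82 ± 0.23. Over all genes, Mt2 was called with KD3010 in 8 of 21 alternatives, Cp and Mcl1 in 7 and Pfkl in 6, with the authors' normalized values among them for each, and with GW1516 Mt2 in 5. Of the alternatives that tested them, 1 called Gstm3 and 0 called G6pc, Sirt1 or Ppargc1b with KD3010. None of the lists these genes belong to passed camera with KD3010 at the settings used, while the list of G6pc and Pfkl, gluconeogenesis and glycolysis, passed fry (adjusted p = 0.0334) with a mean of -0.07 and a median of 0.05, which differ in sign. Among lists that did not pass camera with KD3010, the smallest adjusted p was 0.0658, for xenobiotic metabolism genes (median 0.15) and interferon response genes (median -0.11). Between the agonists, Mcl1 (-0.67 ± 0.18) and Bcl2l1 (-0.64 ± 0.17), both antiapoptotic, were lower with KD3010, as was Pklr (-0.74 ± 0.17), while Mcm6 was higher (0.83 ± 0.17), each adjusted over its list alone, and of these Mcl1 alone was called over all genes in any alternative (6 of 21).

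The 2 arrays of a group differed gene by gene, as for Plin2 with KD3010 (SD 0.57) and Pdk4 with DMSO (SD 0.43). Each of these 2 genes had a single detected probe, so the test of probe pairs below does not cover them. Over 1837 pairs of detected probes of the same gene, the difference between arrays A and B seen by one probe did not track that seen by the other: r was -0.01 with DMSO, 0.02 with KD3010 and -0.026 with GW1516. This is consistent with noise of single probes, for which a correlation of at most 0.1 had been set down beforehand. A criterion first written for an intensity trend compared these values with matched pairs of different genes and could not decide, since both lay near 0. Those matched pairs correlated at 0.042 at most, below the 0.1 set afterwards for a trend. This cannot decide either, because the arrays had been quantile-normalized and the 2 probes of a pair were not matched to each other in signal. The change from DMSO did track between probes of a gene, at r = 0.35 for KD3010 and 0.19 for GW1516, and no biological explanation was tested.

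Some epidermal genes drew notice in the data. Ivl was called with both agonists after background correction and with neither in the authors' normalized values, while Lce1d differed from DMSO by 0.93 ± 0.17 with KD3010 (adjusted p = 0.108, called in 6 of 21 alternatives) and by -0.31 ± 0.17 with GW1516, and Krt17 by 0.66 ± 0.18 (adjusted p = 0.235) and -0.29 ± 0.18. A hypothesis that epidermal differentiation genes may rise together was tested on 11 other such genes, 10 of them detected on both DMSO arrays. The list held 35 genes with a named probe, and those not tested were not detected on both arrays of any group. Their median log2 change was 0.21 with KD3010 (8 of 11 positive, limma's camera adjusted p = 0.0458 over 3 comparisons), between the bounds set beforehand of 0.15 and 0.3, so the test leaves it open, and it was 0.04 with GW1516 (adjusted p = 0.0685). Keratinocytes among the cells are argued against, since 1 of 6 keratinocyte genes, Krt10, was detected on both KD3010 arrays at -0.14 ± 0.17 from DMSO, while Krt5 and Krt14 were not detected on both arrays.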
